A study of Halothece sp. PCC 7418 with 2 samples.

How the data were processed

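RNA of the halotolerant cyanobacterium Halothece sp. PCC 7418 was sequenced from 2 cultures, 1 library per group. The control had grown at 2.0 M NaCl and was taken at 0 h. The other culture was moved from 2.0 M NaCl into fresh medium with 0.5 M NaCl and taken after 24 h. Per the labels' protocols, cells grew at 30 °C under continuous light of 70 µE per square metre and second, and RNA was extracted with TRIzol LS from 100 ml cultures. The treatment label of both samples speaks of an upward salt shift, whereas the titles and the treatment protocol describe a downward one. The titles and protocol were followed here.

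The authors deposited raw read counts per gene, per the file headers, and these counts were the basis of every main value. The submitters' processing notes name Bowtie, with no version. The counting program, its use of strand, its treatment of reads that match several copies and the genome build are not given in the sources used here. The authors also deposited RPKM values, which matched counts divided by gene span and by the library total when recomputed. A further pair of columns held log2 values deposited by the authors, equal to log2 of the count times 1 factor per library plus 1. Those factors equalled the ones of TMM-scaled CPM computed here. The authors' deposited fold change was signed, and its log2 differed from the ratio computed here by a median of 0.0009 and at most 0.178 among the genes analysed. Another 2 columns named for the libraries, holding means, were not used, and neither were the deposited p-values.

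The table held 3723 genes with unique locus tags, of which 3674 were protein-coding, 38 tRNA, 8 rRNA and 3 other RNA genes. No gene had a count of 0 in either library, so a gene without reads in one of them was not analysed here. The control library held 18763268 counted reads and the 24 h library 11555158. Ratios were computed for the 3523 genes with at least 50 reads over both libraries. The other 200 genes were left out.

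Counts were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3. The log2 ratio of 24 h at 0.5 M NaCl over the control was taken with a prior count of 0.5. Each ratio carries an exact Clopper-Pearson 95% interval from the pair of counts. Such an interval covers counting error only, since reads are not independent molecules and 1 library per group shows nothing of the spread between cultures. Its half-width had a median of 0.19 log2 units and a maximum of 1.96. No p-value was computed. Genes were counted by a ratio of at least 2-fold, and separately by whether the whole interval lay past 2-fold.

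Gene product patterns defined 31 gene lists. Each list is described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 10 bins. The percentile describes these 2 libraries and treats genes as separate, although neighbouring genes can share a transcript. Some patterns took in genes of other function, and 43 such memberships were left out in an alternative chosen after the data were seen.

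Named genes followed a rule. It took the 12 highest and 12 lowest ratios among genes with an annotated product, and the 5 genes without one that had the largest absolute ratio. It also took every measured member of the glycine betaine, mycosporine-2-glycine and other compatible solute lists, up to 3 members past 2-fold in each other list, and the 10 genes with most reads in each library. In all, 120 genes were named by it; genes outside it are marked in the text as chosen after their values were seen. The comparisons, lists, thresholds, naming rule and most alternatives were fixed before the data were examined.

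The ratio code was tested on simulated counts for the comparison of 0.5 M NaCl at 24 h with the control, with 200 genes given a true log2 ratio of 2, -2, 3 or -3. Every such gene that passed the count minimum was called 2-fold in the true direction: 50 of 50, 49 of 49, 50 of 50 and 47 of 47. Among 3322 simulated genes without a difference, 3 passed 2-fold, and the intervals covered the true value for 95.5% of genes. These values check the code under counting error. They are not error rates for the real calls, because the spread between cultures is unknown.

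Alternatives were size factors of DESeq2 1.42.0, total counts, upper-quartile scaling, a ribosomal protein median set to 0, and scaling without rRNA, tRNA and the 10 most abundant genes. Others were no count minimum, a minimum of 500 reads, a prior count of 5, the authors' RPKM with 1 added before log2, the authors' fold change, thresholds of 1.5-fold and 4-fold, and unmatched random lists. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.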

Results

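Halothece sp. PCC 7418 is a cyanobacterium that grows over a wide range of salinity and makes the osmolyte glycine betaine and the sunscreen mycosporine-2-glycine. Transcript levels were compared between 1 culture at 2.0 M NaCl, with 18763268 reads counted to genes, and 1 culture moved to 0.5 M NaCl for 24 h, with 11555158 reads. The comparison asks which transcripts differ after a salt down-shift, with attention to both compounds. No difference has a replicate check, and 24 h in fresh medium came together with the lower salt. Values are log2 ratios of 24 h over control, with the 95% counting interval in brackets.

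Of the 6 measured genes for glycine betaine uptake and synthesis, 2 were at least 2-fold lower at 24 h and 0 higher. The betaine transporter PCC7418_3058 (bases 3309466 to 3311160) had 17750 reads in the control and 1005 at 24 h, a log2 ratio of -3.11 [-3.20 to -3.02], or 8.64-fold lower. The sarcosine/dimethylglycine N-methyltransferase PCC7418_3511, which adds the later methyl groups of glycine betaine, was at -1.79 [-1.88 to -1.70]. The adjacent glycine/sarcosine N-methyltransferase PCC7418_3510, which acts first, was at -0.45 [-0.50 to -0.39] and so below 2-fold. The transporter components PCC7418_0112, PCC7418_2218 and PCC7418_3406 were at -0.31, -0.22 and 0.53. The list median of -0.38 lay at percentile 14.2 of the random lists.

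The 4 genes taken for mycosporine-2-glycine synthesis did not share a direction. PCC7418_1590, annotated as a 3-dehydroquinate synthase, was at -2.05 [-2.24 to -1.86], from 2104 to 249 reads. PCC7418_1077 and the O-methyltransferase PCC7418_1078 were at -0.76 [-1.36 to -0.22] and -0.57 [-0.81 to -0.35]. The D-alanine ligase family gene PCC7418_1076, from the same strand and region as those, was higher at 1.33 [1.15 to 1.51]. Its end overlaps a gene on the opposite strand, and without known strand use reads of the overlap cannot be assigned. With total counts its ratio was 0.997, just under 2-fold. Among other compatible solutes, sucrose synthase PCC7418_2272 was at -1.87, with an interval half-width of 0.13. Sucrose phosphatase PCC7418_1364 at -0.50 [-1.39 to 0.27] and glucosylglycerol phosphatase PCC7418_2274 at -0.24 [-0.92 to 0.38] had intervals that included 0.

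Genes that supply glycine and methyl groups stood lowest of the 31 lists. Of 12 measured members, 8 were at least 2-fold lower and 0 higher, and the median of -1.21 lay at percentile 0.02. Adenosylhomocysteinase PCC7418_3684, which removes the by-product of methylation, was at -3.07 [-3.11 to -3.03], from 89951 to 5225 reads. Serine hydroxymethyltransferase PCC7418_1525, a source of glycine and one-carbon units, was at -3.06 [-3.15 to -2.98], and aminomethyltransferase PCC7418_0371 at -2.54 [-2.73 to -2.35]. Chosen after their values were seen, methylenetetrahydrofolate reductase PCC7418_0548 was at -2.50 and methionine adenosyltransferase PCC7418_2062 at -2.36, whereas the second annotated methionine adenosyltransferase PCC7418_3028 was at -0.05.

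**Figure D1:**
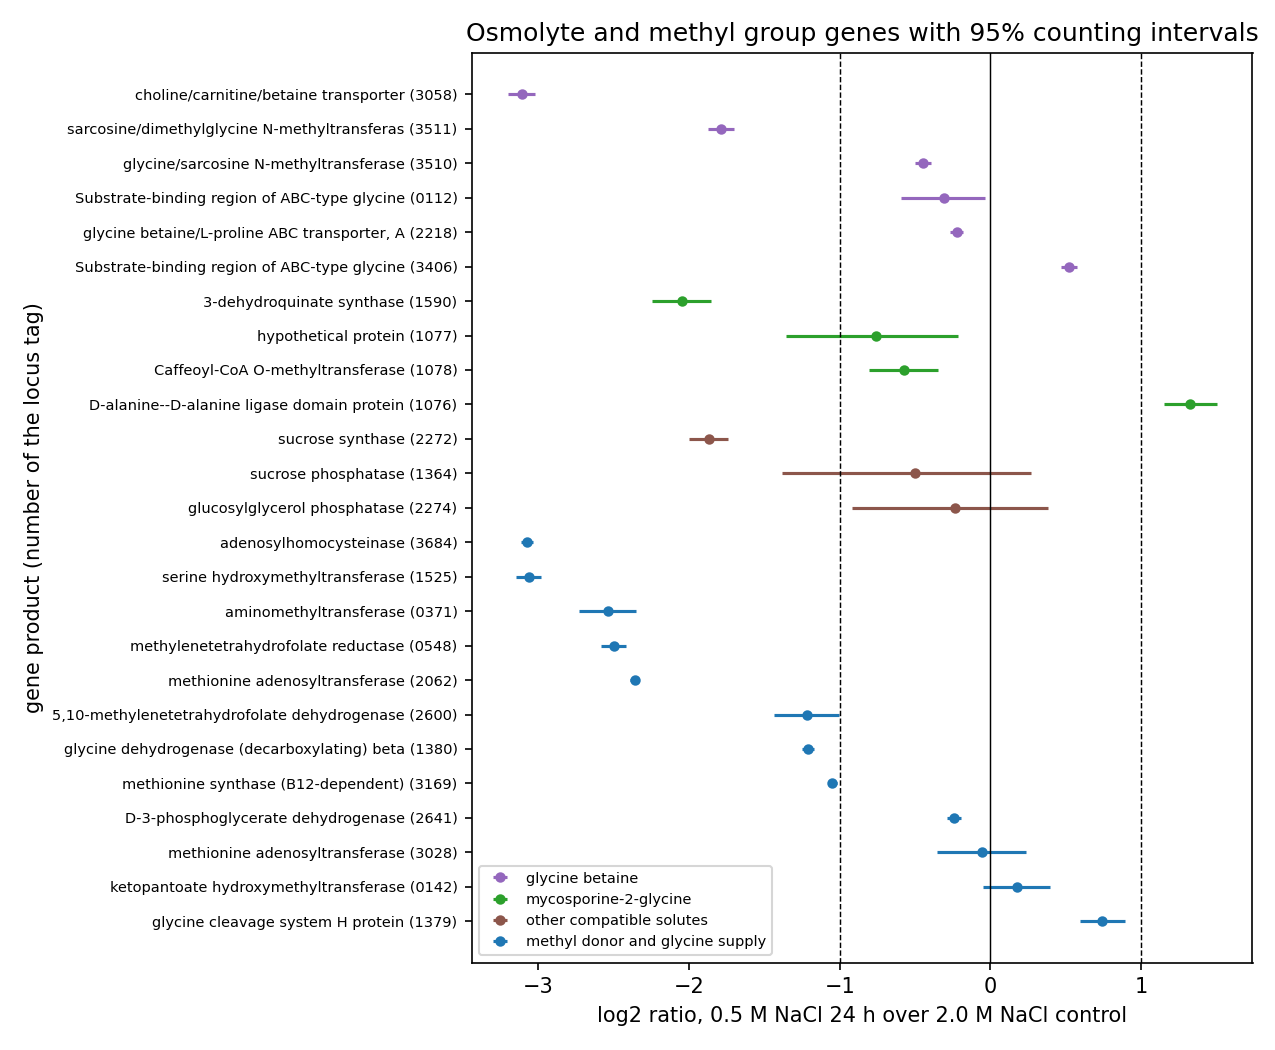
Log2 ratio of 24 h at 0.5 M NaCl over the 2.0 M NaCl control on the horizontal axis, for each measured gene of 4 lists; points are single ratios from 1 library per group and bars are 95% counting intervals. Dashed lines mark 2-fold; 8 of the 12 methyl donor and glycine supply genes lie at or below the lower line.

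Over all 3523 genes, 587 (16.7%) were at least 2-fold higher and 517 (14.7%) at least 2-fold lower, and the whole counting interval lay past 2-fold for 12.3% and 9.99% of all genes. Scaling by total counts lowered every ratio by 0.33, giving 368 higher and 821 lower, so that 31.0% of the calls were higher instead of 53.2%. At least 8-fold differences were found for 35 higher and 23 lower genes. Of the 3523 genes, 1125 had no annotated function, and these made up 224 of the higher and 155 of the lower ones.

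**Figure D2:**
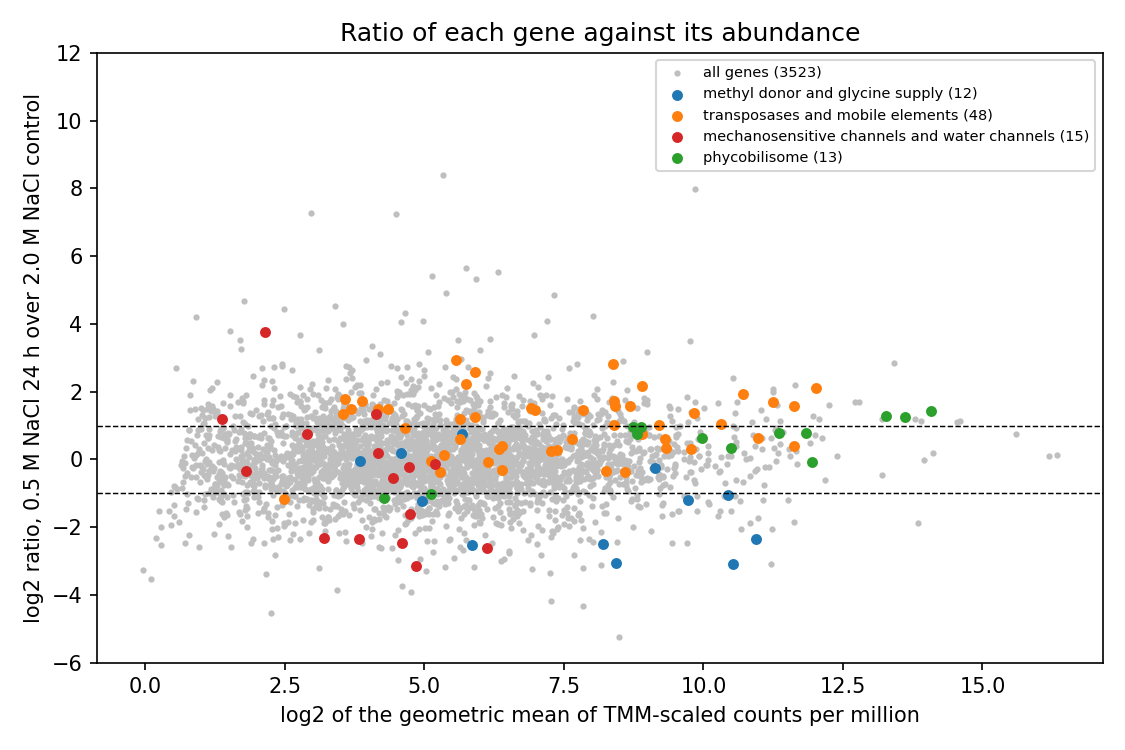
Log2 ratio of each of 3523 genes against the log2 geometric mean of its TMM-scaled CPM; grey points are all genes, colours mark 4 lists, and dashed lines mark 2-fold. Methyl donor and glycine supply genes lie mostly below the lower line, and 27 of 48 transposase and mobile element genes lie above the upper one.

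The highest annotated ratios came from a few gene neighbourhoods. The flavin reductase domain genes PCC7418_1460 and PCC7418_1462, whose best matches are the flavodiiron proteins dfa4 and dfa2, were at 5.53 [5.35 to 5.72] and 4.86 [4.75 to 4.98]. Their neighbour PCC7418_1463, annotated as a nitrogenase family protein, was at 5.66. Glycogen phosphorylase PCC7418_2869, which releases glucose phosphate from glycogen, was at 5.40 [5.14 to 5.69], phosphoketolase PCC7418_2870 at 5.32, phosphoglycerate mutase PCC7418_2871 at 4.06 and the efflux transporter subunit PCC7418_2872 at 4.09. The two-component genes PCC7418_0632 and PCC7418_0633 were at 4.52 and 4.68, the latter from 14 and 181 reads. The peptidoglycan-binding domain gene PCC7418_3818 was at 4.33, the sulfate transporter family gene PCC7418_0979 at 4.24 and the sodium/proton antiporter PCC7418_0978 at 4.07. In choosing these 12 genes, 7 unannotated ones with ratios as high were passed over.

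At the other end, the FtsH membrane protease gene PCC7418_0280 was at -5.25 [-5.37 to -5.13], from 46473 to 597 reads, or 38.1-fold lower. The sugar transporter genes PCC7418_0883 and PCC7418_0881 were at -3.91 and -3.20, the M22 glycoprotease PCC7418_2845 at -3.84 and glycerol-3-phosphate dehydrogenase PCC7418_2069 at -3.35. Glycosyl transferases PCC7418_1201 and PCC7418_2999 were at -3.38 and -3.17, the PfkB family gene PCC7418_0391 at -3.20, rhodopsin PCC7418_3250 at -3.18 and the MscS channel PCC7418_3672 at -3.15. The cobalt transport gene PCC7418_3240 rested on 68 and 3 reads, with a ratio of -3.26 [-5.78 to -1.86]. Again 7 unannotated genes were passed over. Of the unannotated genes, PCC7418_0631 at 8.40, PCC7418_2597 at 7.98, PCC7418_1461 at 7.26, PCC7418_0630 at 7.25 and PCC7418_1459 at 4.91 had the largest absolute ratios. PCC7418_2597 went from 1224 to 150850 reads, whereas PCC7418_1461 and PCC7418_0630 had 13 and 38 reads in the control.

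Ion transport genes did not share a direction. Of 26 measured sodium and potassium transport genes, 8 were at least 2-fold higher and 4 lower, with a median of -0.01; with total counts it was 6 and 7. The higher ones included PCC7418_0978 and the multisubunit antiporter genes PCC7418_0976 at 3.53 [3.35 to 3.71] and PCC7418_0974 at 2.77 [2.29 to 3.30]. These named genes lie in 1 stretch of 10 higher genes on the minus strand, PCC7418_0970 to PCC7418_0979, found after the values were seen. It holds further multisubunit antiporter genes, and neighbours can share a transcript, so the 8 higher genes need not be separate responses. Of the 4 lower genes of the list, 1 is a nucleic acid binding protein that the name pattern took in. Of 15 mechanosensitive and water channel genes, which release solutes when membranes are stretched or pass water, 6 were lower and 3 higher, with a median of -0.33 at percentile 13.7. Among the 10 with at least 500 reads, 5 were lower and 1 higher, and the median of -1.08 lay at percentile 0.16. However, 4 mechanosensitive channel genes lie in 1 lower stretch, PCC7418_3670 to PCC7418_3674, found after the values were seen, with a median of -2.34. The percentile treats them as separate genes, and the list was not recomputed without the stretch. PCC7418_3672 and PCC7418_3673 were at -3.15 and -2.62, and PCC7418_2875 at 3.76 [3.17 to 4.45]. In the sulfate uptake list, PCC7418_0979 was at 4.24 and PCC7418_1543 at -1.48.

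Genes of the light-harvesting phycobilisome had a median of 0.78 (percentile 97.2), with 3 of 13 at least 2-fold higher and 2 lower. The percentile was 97.7 without a count minimum, 97.8 with at least 500 reads and 98.9 against unmatched lists, and with total counts 1 gene was higher and 2 lower. Phycocyanin subunits PCC7418_3214 and PCC7418_3213 were at 1.44 and 1.26 and the linker PCC7418_3212 at 1.29. With total counts the latter 2 were at 0.93 and 0.96, below 2-fold. The 3 higher genes are neighbours on the minus strand and can share a transcript, while the percentile treats them as separate. Photosystem I had 11 of 14 genes within 2-fold; PsaK, PCC7418_1523, was at 1.64, while PCC7418_0520 and PCC7418_0673 were at -1.49 and -1.36. In photosystem II, 6 of 29 were higher and 5 lower, whereas with total counts or the authors' RPKM 1 was higher and 6 lower. The D1 protein genes PCC7418_3853 and PCC7418_2976 were at -2.48 and -2.07 and a further copy, PCC7418_2704, at -0.02, or 0.06 with the ribosomal protein median at 0. Ratios of such copies are uncertain, because the treatment of shared reads is not given in the sources used here. PsbP, PCC7418_2285, was at -1.88.

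Pigment genes included 8 of 32 chlorophyll and haem synthesis genes at least 2-fold lower and 3 higher. Sirohydrochlorin ferrochelatase PCC7418_3611, which makes sirohaem and not haem, was at -2.95, PCC7418_1057 of protochlorophyllide reductase at -2.06 and the cyclase PCC7418_1706 at -1.80. The orange carotenoid protein genes PCC7418_3193 and PCC7418_2000 were at 1.52 and 1.10, and the high-light protein gene PCC7418_2745 at -2.06. With total counts PCC7418_2000 was at 0.77, and 1 gene of the carotenoid and high-light list was higher and 2 lower, against 2 and 1 in the main scaling.

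Electron transport and NDH genes had a median of -0.39 at percentile 1.57, although 25 of 30 were within 2-fold. Against unmatched random lists it lay at percentile 3.14, and with total counts 2 genes were higher and 7 lower, against 3 and 2. The NdhF3 family gene PCC7418_3478 and its neighbour PCC7418_3477 were 3.27-fold and 2.84-fold higher, and PCC7418_2210, subunit M, was at -1.68. With them, the CO2 hydration gene PCC7418_3476 was at 1.81 [1.77 to 1.86], and the carboxysome gene PCC7418_3533 at 1.13, or 0.79 with total counts. PCC7418_3476 and PCC7418_3533 were the 2 of 9 carbon fixation and carbon concentration genes past 2-fold, and that list had a median of 0.41 at percentile 80.04. Oxidative stress genes had a median of -0.48 at percentile 0.87, with 6 of 31 lower and 1 higher. The glutaredoxin-like gene PCC7418_0718 was at -1.97, PCC7418_0758 of ferredoxin thioredoxin reductase at -2.25 on 131 and 13 reads, and the arsenate reductase PCC7418_1154, not an antioxidant enzyme, at -2.52 on 64 and 5 reads. ATP synthase genes PCC7418_2526, PCC7418_2527 and PCC7418_2524 were at 2.73, 2.64 and 1.43, and 11 of 16 genes of that list were within 2-fold. These named genes belong to a second set of ATP synthase subunits in 1 run of neighbouring genes, with 1 annotated as an alternate F1F0 ATPase. Without genes of other function, left out after the data were seen, 4 genes of the list were higher and 0 lower.

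**Figure D3:**
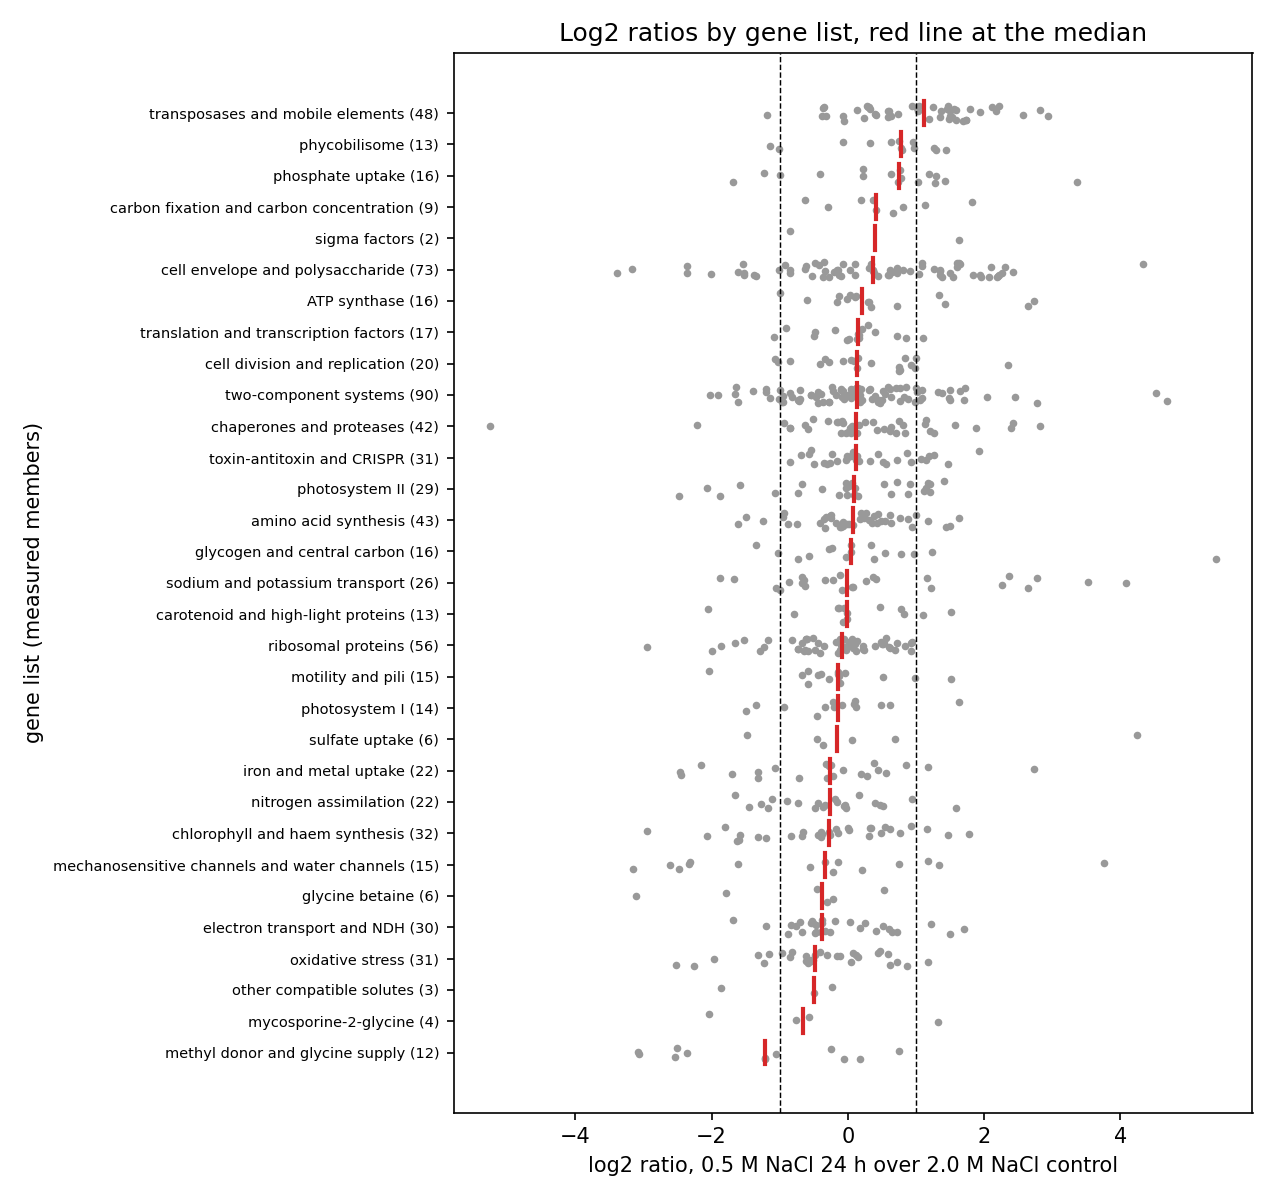
Log2 ratio of 24 h over control for every measured member of the 31 lists, 1 point per gene with vertical scatter added for display; red lines are list medians and dashed lines mark 2-fold. Medians run from -1.21 for methyl donor and glycine supply to 1.12 for transposases and mobile elements.

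Transposase and mobile element genes had the highest median of the 31 lists, 1.12, at percentile 100.0 of the random lists. At least 2-fold higher were 27 of 48 and lower was 1; without 1 gene of other function, left out after the data were seen, it was 26 of 47. PCC7418_2726, PCC7418_2857 and PCC7418_1632 were at 2.94, 2.82 and 2.58. Members of one family can share reads, so single ratios are uncertain. The count of higher genes and the percentile treat members as separate genes, so the same limit holds for them. Phosphate uptake genes had a median of 0.75 at percentile 99.0, with 6 of 16 higher and 2 lower. With total counts 2 were higher and 3 lower, and with the authors' RPKM 1 and 3. Alkaline phosphatase PCC7418_3485 was at 3.36, and the transporter genes PCC7418_1747 and PCC7418_1748 at -1.68 and 1.43, the latter 0.80 with the authors' RPKM. PCC7418_1748 rested on 31 and 41 reads, with an interval from 0.73 to 2.16. The cell envelope and polysaccharide list, with 26 of 73 higher and 12 lower, had a median of 0.37 at percentile 99.6. Without its 12 members in 1 run of neighbouring genes, an alternative chosen after the data were seen, the median was 0.04 at percentile 64.2. With at least 500 reads per gene the list lay at percentile 86.1.

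Among chaperones and proteases, 9 of 42 were higher and 2 lower, but 5 and 5 with total counts or the authors' RPKM. Hsp20, PCC7418_1472, was at 2.82 and Cpn10, PCC7418_1357, at 2.42, while FtsH PCC7418_0280 was the lowest. Ribosomal proteins had 8 of 56 lower and 0 higher and a median of -0.08 at percentile 28.4, with S15 PCC7418_0748 at -2.94, L34 PCC7418_0894 at -1.99 and S6 PCC7418_1475 at -1.86. RNA polymerase subunits PCC7418_1068 and PCC7418_2118 were at 1.11 and -1.08; the former was at 0.78 with total counts, and the latter just under 2-fold with the ribosomal protein median at 0. In nitrogen assimilation, with 5 of 22 lower and 1 higher, PCC7418_2412 was at -1.65, PCC7418_1265 at -1.45 and the P-II regulator PCC7418_0134 at 1.59. In the iron and metal list the members with the largest ratios were NifH, PCC7418_1785, at 2.73, a nitrogenase subunit, and the hydrogenase genes PCC7418_3034 and PCC7418_3036 at -2.47 and -2.45, none of them a metal transporter.

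In 6 further lists most genes were within 2-fold. Glycogen and central carbon had 12 of 16 so, with transaldolase PCC7418_2168 at -1.35 and pyruvate kinase PCC7418_1489 at 1.24, or 0.91 with total counts. Two-component systems had 62 of 90, with PCC7418_2868 at 2.77; cell division and replication 16 of 20, with FtsK PCC7418_1390 at 2.35, DnaA PCC7418_0004 at -1.07 and gyrase PCC7418_0128 at -1.03. With the ribosomal protein median at 0 both were below 2-fold, at -0.99 and -0.95. DnaA rested on 79 and 18 reads, with an interval from -1.93 to -0.35. Motility and pili had 13 of 15, with PCC7418_3369 at -2.04 and PCC7418_0137 at 1.51. Toxin-antitoxin and CRISPR had 25 of 31, with PCC7418_1283, PCC7418_3175 and PCC7418_1437 at 1.92, 1.47 and 1.27. PCC7418_1437 was at 0.94 with total counts and PCC7418_3175 at 0.99 with the authors' RPKM. PCC7418_3175 rested on 22 and 30 reads, with an interval from 0.64 to 2.34. Amino acid synthesis had 36 of 43, with chorismate lyase PCC7418_1938 at -1.62, aminodeoxychorismate lyase PCC7418_1660 2.83-fold higher and the regulatory kinase PCC7418_0269 at 1.63. Without genes of other function, left out after the data were seen, 23 of 28 were within 2-fold, 2 higher and 3 lower. The kinase PCC7418_0269 was also 1 of the 2 measured genes of the sigma factor list. The other was within 2-fold at -0.84, but at least 2-fold lower with total counts or the authors' RPKM.

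The 10 genes with most reads took 34.3% of the control library and 37.6% of the 24 h library. Photosystem I genes psaB, PCC7418_0289, and psaA, PCC7418_0290, led both and were at 0.12 and 0.10. The Rubisco large subunit PCC7418_3537 was at 0.19. With total counts these 3 took the other sign, at -0.21, -0.23 and -0.14, and likewise with the authors' RPKM. PCC7418_0334 was at 0.74 and the AAA ATPase PCC7418_1199 at -0.46. The secretion pathway gene PCC7418_1294 went from 593688 to 78322 reads, a ratio of -1.89. PCC7418_0056, annotated as of unknown function, went from 85649 to 301518 reads, at 2.85. The photosystem II genes PCC7418_2390 and PCC7418_2389 were at 1.12 and 1.21, RNase P RNA, PCC7418_R0051, at 1.11 and PCC7418_0071 at 1.13; with total counts these 4 were at 0.79, 0.88, 0.78 and 0.80, below 2-fold.

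**Figure D4:**
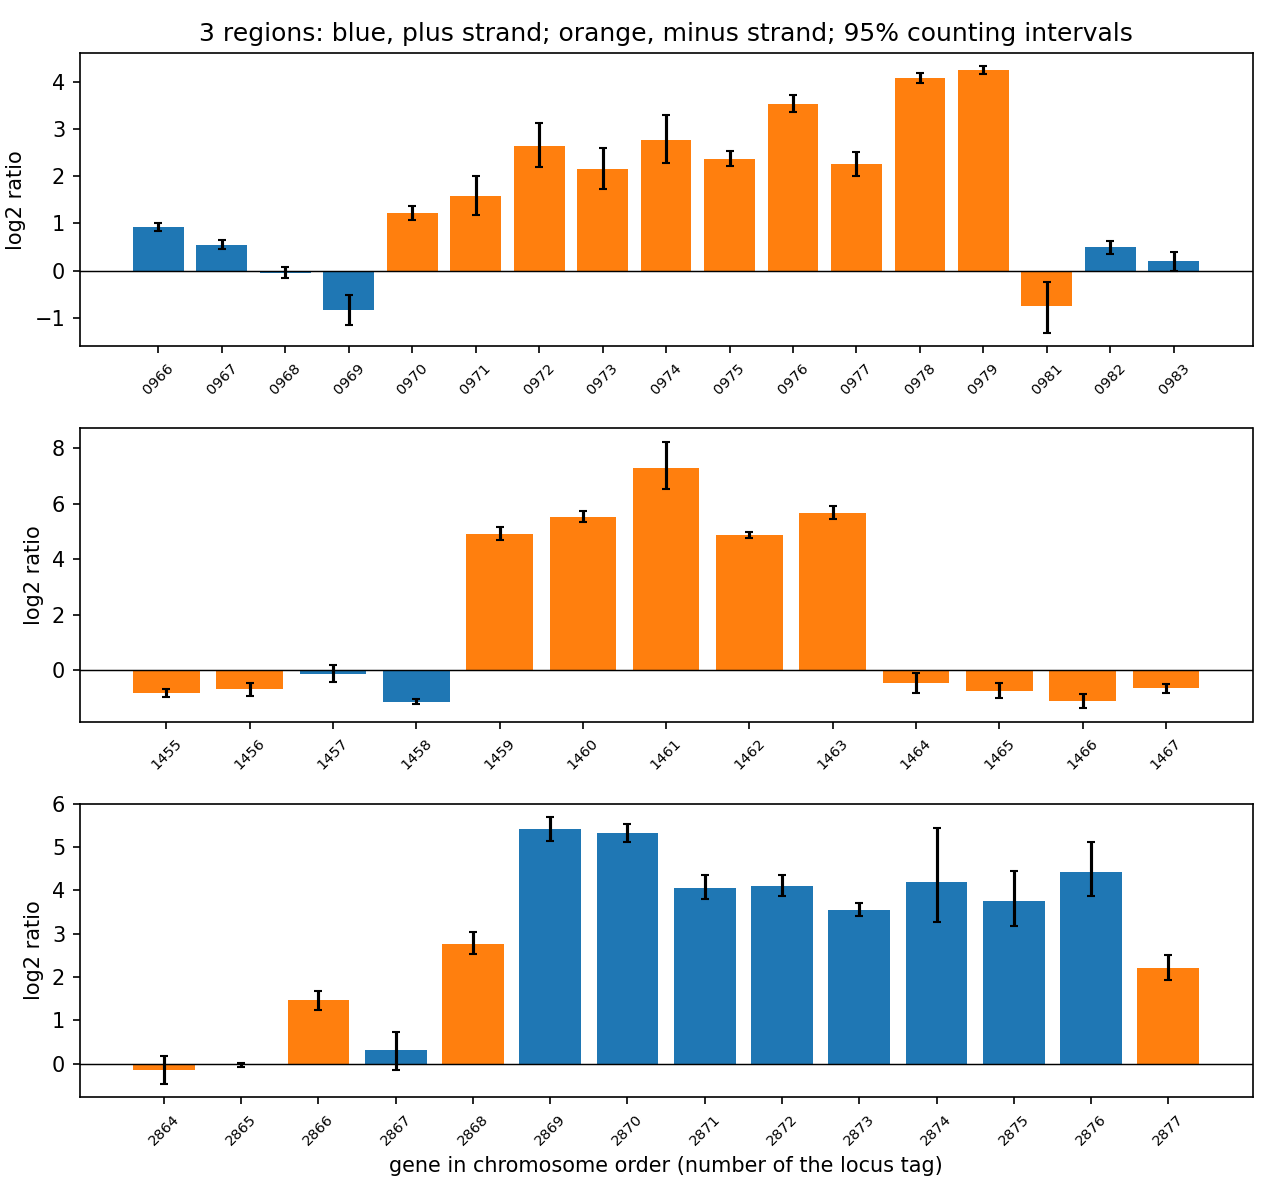
Log2 ratio of 24 h over control for neighbouring genes in 3 regions chosen after their values were seen, in chromosome order, with 95% counting intervals as error bars; blue bars are plus-strand and orange bars minus-strand genes. The 10 genes from PCC7418_0970 to PCC7418_0979 lie between 1.22 and 4.24, and the 5 genes from PCC7418_1459 to PCC7418_1463 between 4.86 and 7.26.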

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

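The alternative of lists without genes of other function and that of the envelope list without its run were chosen after the data were seen. No paired analysis was possible because each group has 1 library, and no significance test between the groups was run. Summing several table entries per gene was not run, since locus tags were unique. The total of 1104 genes past 2-fold stayed between 753 and 1189 under every scaling, count minimum, prior count and deposited value. Its division moved: total counts, which shift every ratio by -0.33, gave 368 higher and 821 lower genes. The authors' RPKM, also without a composition factor but with 1 added before log2, gave 339 higher and 762 lower. That RPKM is scaled by total counts too. Its difference from 368 and 821 therefore came with the 1 added in place of the prior count. A minimum of 500 reads left 2451 genes and 384 higher. By construction, a threshold of 1.5-fold gave 1905 genes, 986 higher and 919 lower, and 4-fold gave 229, 118 and 111. The number of lists with a median among the lowest or highest 2.5% of random lists was 6, and 6 or 7 under the alternatives that kept all genes of each list or left out those of other function. Without the run of neighbouring genes in the envelope list it was 5. Of the main 6 lists, 5 stayed there with at least 500 reads, which lost the envelope list, and 5 against unmatched lists, which lost electron transport and NDH. Of the 106 named genes past 2-fold, 94 stayed so with total counts, 91 with the authors' RPKM, 103 with the ribosomal protein median at 0, and none of these turned sign in any alternative. With total counts, 9 lists with medians near 0 took the other sign. Depth limits genes with few reads in one library, where interval half-widths reached 1.96.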

Other observations

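The tests of the copies of transposases, of scaling and of fresh medium for the inorganic carbon genes, and of neighbouring genes were chosen after the results were seen. Genes in this part were likewise chosen after their values were seen. The longest stretch of neighbouring genes on 1 strand that were all at least 2-fold higher held 40 genes, from PCC7418_1858 to PCC7418_1897 (bases 2028304 to 2077766). Their median log2 ratio was 1.94, with a range from 1.08 to 2.72. Of these, 12 were members of the cell envelope and polysaccharide list. Another such stretch, PCC7418_2523 to PCC7418_2528, codes for a second set of ATP synthase subunits and had a median of 2.68. The hydrogenase genes PCC7418_3034 to PCC7418_3038 were lower together, with a median of -2.15, as were 4 mechanosensitive channel genes within PCC7418_3670 to PCC7418_3674, a stretch with a median of -2.34.

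Over the 3723 genes with deposited counts, 9 stretches of at least 5 such genes were higher and 6 were lower, holding 93 and 34 genes. Genes absent from the deposited counts were not seen, so neighbours here can have such a gene between them. The hypothesis that genes of 1 transcription unit respond together was tested on neighbour pairs. On the same strand, 297 of 2170 pairs (13.7%) were both past 2-fold in one direction, against a highest value of 136 in 1000 shuffles of the ratios. On opposite strands it was 62 of 1198 pairs (5.2%). These values are consistent with shared transcripts, found and tested on the same data.

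Of the transposase and mobile element list, 27 of 48 genes were higher at 24 h, or 26 of 47 without 1 gene of other function. Genomic DNA in the 24 h library would add about the same RPKM to every gene of 1 copy. Of the 27, 100.0% gained more than 3.86, the RPKM of the 5th percentile of all genes. A gain was partly fixed by choosing genes that were 2-fold higher. For genes with several copies DNA could add more, depending on the treatment of shared reads, which is not given. The values thus speak against genomic DNA only for genes of 1 copy, and which of the 27 have 1 copy was not determined. A single element whose reads were shared over all copies would give nearly 1 ratio, but the ratios had an SD of 0.91. The list holds more than 1 transposase family, so a spread was likely in any case. The SD speaks only against 1 element behind all 48 genes. Sharing within single families stays open, and so does a response to the salt shift, which was not tested against other causes.

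A set of 8 genes put together after their values were seen, for inorganic carbon uptake and flavodiiron proteins, was higher, from 2.84-fold for PCC7418_3477 to a log2 ratio of 7.26 for PCC7418_1461. The set takes in PCC7418_0056 and PCC7418_0979 for their resemblance to bicarbonate transporter families and PCC7418_1461 for its place between flavodiiron genes, and it is not evidence for a pathway. The list fixed for carbon fixation and carbon concentration had 2 of 9 genes higher and a percentile of 80.04. The lowest ratio of the 8 over the scalings was 1.17, so all stayed past 2-fold. Each scaling shifts all genes alike, and the median ratio of all genes was -0.019 in the main scaling. It moved by -0.33 with total counts and by 0.08 with the ribosomal protein median at 0. The 8 genes were chosen for high ratios and each scaling shifts them alike, so this outcome was fixed by that choice. The values therefore cannot decide whether scaling lies behind the higher ratios, and they decide nothing about other causes. With 0 libraries of a mock transfer into fresh 2.0 M NaCl medium, an effect of fresh medium and time cannot be told apart from that of the lower salt.

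Of the ribosomal protein genes, 8 were at least 2-fold lower, and these had a median span of 286.5 bases against 379.5 for all of them. A bias by gene length does not account for this: after the running median over length was subtracted, 100.0% of the 8 were still 2-fold lower. That running median lay between -0.11 and 0.06 at these genes. The 8 make up 14.3% of the list, against 14.7% lower among all genes, and the list median of -0.08 lay at percentile 28.4. By these values the list does not stand apart. However, 0 of its 56 genes were at least 2-fold higher, against 16.7% of all genes.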
